A study of Rattus norvegicus with 10 samples.

How the data were processed

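RNA from RPE-J cells was sequenced from polyA-selected libraries, 1 per condition, in 10 conditions. Cells had been removed from flasks with trypsin before RNA extraction, per the labels' protocols. Per the submitters' processing notes the tools named were Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2 and DESeq2 without a version; the genome build, the annotation and the strand setting are not given in the sources used here. The authors deposited 39 tables, each for 1 pair of libraries. Each deposited table gives, per the file headers, a log2 fold change, a p-value, an adjusted p-value, a level for each of the 2 libraries and the gene name beside an Ensembl gene identifier. The level is a signal that is never negative, and the deposited values behave as read numbers divided by a size factor that is set anew in each table.

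The tables list between 13015 and 13781 genes, with lowest mean levels between 8.32 and 10.5, so genes below such a level were not analysed here and the sums of reads are reads in listed genes, not library depth. In each column the value of 1 read was taken as the step of which the values are multiples. Dividing by it gave read numbers of which 100% lay within 0.01 of a whole number, with a largest deviation of 6.64e-05, and 0 gene values differed between tables of the same library. No count model was run on these read numbers; they were used for intervals and to scale all libraries together by the median of ratios. Reads were found in all 10 libraries for 13391 of the 14119 genes listed, and 11188 of these had a mean level of at least 50. The deposited log2 fold change equalled the log2 ratio of the deposited levels within 5.36e-05, second library over first, so fold changes were computed from the levels. Columns carry library numbers. For 9 of them the number is tied to a sample by the file records, and the remaining number was assigned to the remaining sample, PNU 12 h. Gene names are those in the tables: 61 are carried by more than 1 gene and were left out of gene lists, and 20 had been turned into dates. The reference table of rat genes was not used here.

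With 1 library per condition no test between conditions was made and no p-value across genes was computed. For each comparison genes were counted by a size rule, at least 2-fold and a mean level of the 2 libraries of at least 50, in each direction. The fold came from the table of the pair, except for nicotine 12 h against 1 h and MLA 12 h against 1 h, for which levels scaled over all libraries were used. Levels set across libraries were scaled over all libraries, while folds and the levels beside them come from 1 table. Adjusted p-values in the authors' deposited tables were counted under 0.05 and named as theirs; over all 39 tables the lowest was 0.999715, and the largest gap to a Benjamini-Hochberg adjustment of the deposited p-values was 9.13e-10. Intervals of folds are exact binomial (Clopper-Pearson) 95% intervals of the reads of 2 libraries, and intervals of levels are exact Poisson intervals. Reads are not independent molecules, so both cover counting error only.

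Before the data were examined, 37 gene lists with 866 genes were fixed, along with the comparisons, the size rule, the alternatives and the rule for named genes. Lists were described by the median log2 fold of members at a mean level of at least 10 and set against 10000 random lists of the same size matched on mean level in 20 bins; lists with fewer than 5 measured members got no such rank. The lists cover immediate early, ERK feedback, EGF family, progenitor, Notch, Wnt, BMP and TGF-beta, FGF, JAK-STAT, NF-kB, interferon, ER stress, heat shock, cholesterol synthesis, hypoxia and glycolysis, NRF2, metallothionein, AhR, circadian, glucocorticoid, S phase, G2/M, p53, RPE, mesenchymal and matrix, nicotinic and muscarinic receptor, glial, photoreceptor, neuron, fibroblast, endothelial, immune, mitochondrially encoded, ribosomal protein, oxidative phosphorylation and calcium and cAMP genes, and a set of RNA quality genes of which 0 of 7 were measured. The text names, per comparison, genes from the top of the 10 highest and 10 lowest folds past the size rule that carry a gene name, leaving out entries under clone, sequence or locus numbers. Members of a gene family with near-identical copies, such as histone and ribosomal protein genes, share reads, and their values are uncertain. It also names up to 4 members of a list with the largest folds at a mean level of at least 50, the genes with the largest range over the PNU libraries, and Hbegf, Chrna7 and Rpe65. Some genes that this rule names are left out of the text. The genes that comparisons share and the levels of markers were chosen for the text after their values were seen.

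The procedure was tested on simulated data for PNU 12 h against DMSO 12 h, with Poisson counts for 13391 genes and 200 changed genes. All 100 genes changed 3-fold passed the size rule, 1 of 100 changed 1.5-fold did, and 0 of 11092 unchanged genes did. The intervals held the true fold in 95.25% of genes, and 1 of 200 unchanged lists lay outside the ranks from 0.5% to 99.5%. Poisson counts hold counting error only. In the real pair the median squared log2 fold, relative to counting error, was 6.29 times the value for counting error alone. Over all comparisons this ratio ran from 2.48 to 27.4. The simulated rates therefore do not carry over to these libraries. For the shared DMSO library, 100 sets of unchanged libraries were simulated, with the spread between the 3 treated 12 h libraries as noise. Alternatives were a 1.5-fold rule, mean levels of at least 10 or 200, recentring on the median gene, folds taken through another library, a pseudocount of 10, and for lists the mean, unmatched random lists and members at a mean level of at least 50. Added after seeing the data were alternatives without PNU 3 h, without nicotine 1 h and PNU 3 h, with PNU and MLA only, and with PNU 30 min in place of DMSO 12 h, and for the PNU time course the 1.5-fold rule and the mean level of at least 10. No replicate could be left out. The 1 h and 12 h libraries of each compound were compared within the compound, and a joint fit of compound and time over these 6 libraries, which would take the compounds as replicates of each other, was not run. Gene length and GC content were not tested here. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.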

Results

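The series profiled polyadenylated RNA from RPE-J cells, a rat retinal pigment epithelium line transformed with the SV40 virus. The cells were exposed to PNU-282987 (PNU below), an agonist of the α7 nicotinic acetylcholine receptor, at 100 nM, to nicotine at 1 µM as the receptor activation control, to MLA at 100 nM as the negative control, or to the vehicle DMSO. There were 10 libraries, 1 for each condition: DMSO at 12 h, PNU at 30 min, 1 h, 3 h, 8 h and 12 h, and nicotine and MLA at 1 h and 12 h. With 1 library per condition no difference below has a replicate check, and each comparison describes 2 libraries, not 2 conditions. The authors' p-values, counted below for their deposited tables, also set 1 library against 1. They had no replicate from which to estimate spread, so those counts show neither that genes differed nor that they did not. The reads in the listed genes numbered 15220638 in PNU 8 h, 20740579 in PNU 3 h, 22015742 in DMSO 12 h, 22280521 in PNU 30 min and 22832771 in MLA 1 h. They numbered 25383582 in nicotine 12 h, 25523823 in PNU 1 h, 26283462 in nicotine 1 h, 29545212 in PNU 12 h and 31510333 in MLA 12 h. Genes were counted as different when the 2 libraries differed at least 2-fold and their mean level was at least 50 normalised reads. Intervals are 95% intervals for counting error only.

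Few genes differed at least 2-fold between any of the libraries. At 1.5-fold there were more, with a median of 277 over the pairs and 1646 between nicotine 1 h and nicotine 12 h. Over the 45 pairs of libraries, a median of 41 genes differed at least 2-fold among 11149 to 11216 genes at a mean level of at least 50, with a range from 0 to 294. The closest pair was MLA 12 h and nicotine 12 h, with 0 genes past 2-fold and 59 past 1.5-fold, followed by MLA 12 h and PNU 8 h with 1 gene. DMSO 12 h was closest to PNU 30 min, at 6 genes. Nicotine 1 h stood farthest from the rest, with a median of 152 genes over its 9 pairs, and its closest libraries were PNU 3 h (13 genes) and PNU 12 h (15 genes). Without nicotine 1 h and PNU 3 h the median over the remaining pairs was 24.5 genes. These counts use levels scaled over all libraries and so differ slightly from the counts of single comparisons below.

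**Figure D1:**
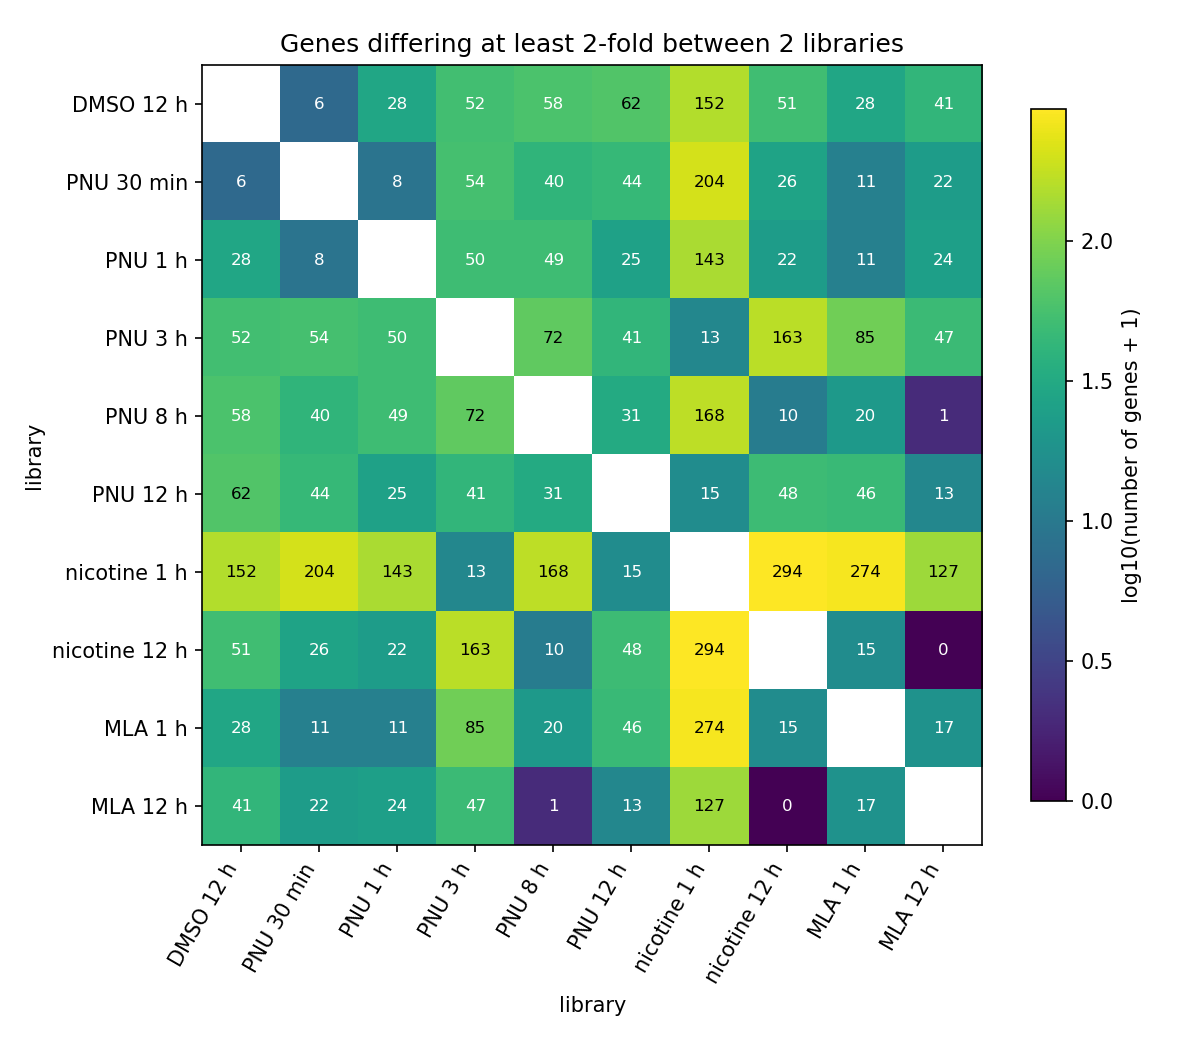
Number of genes that differed at least 2-fold, at a mean level of at least 50 normalised reads, for each pair of the 10 libraries (both axes; colour on a log10 scale). MLA 12 h and nicotine 12 h differed in 0 genes, whereas nicotine 1 h and nicotine 12 h differed in 294.

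Hbegf, the gene of heparin-binding EGF-like growth factor, was highest in the DMSO 12 h library, at 2960 normalised reads (95% Poisson interval 2850 to 3072). It was lowest in PNU 1 h, at 1788 (1709 to 1870). The other 8 libraries lay between, with 2358 in PNU 30 min, 2295 in PNU 3 h, 2124 in PNU 8 h and 2002 in PNU 12 h. Nicotine gave 2353 at 1 h and 1966 at 12 h, and MLA gave 2056 at 1 h and 1999 at 12 h. Among nicotinic receptor subunits Chrnb1 was the most abundant, at 424 (nicotine 12 h) to 509 (PNU 3 h) normalised reads. Chrna5 lay between 36.7 in PNU 30 min and 64.1 in MLA 12 h, and the counting intervals of these 2 libraries (25.6 to 51.1 and 51.4 to 79.1) were the only ones that did not overlap. Chrna7, the gene of the α7 subunit, and Rpe65, the retinoid isomerase of the visual cycle, had no value in the tables used, which list only genes above a low mean level, and were not analysed here.

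The first question of the design was how the cells differed after 12 h of the α7 agonist from cells given vehicle for the same time. In PNU 12 h against DMSO 12 h, genes of cholesterol synthesis and immediate early genes were lower, and targets of the aryl hydrocarbon receptor (AhR) were higher. On 17 genes chosen from PNU 30 min, 8 h and 12 h, however, DMSO 12 h lay near PNU 30 min, at -0.046. The scale sets PNU 30 min at 0 and PNU 12 h at 1, and MLA 12 h and nicotine 12 h lay at 0.921 and 0.970. Without the cholesterol list these 3 values were 0.152, 0.877 and 0.697. A wrong label, early collection or no change of medium may account for this, so DMSO 12 h may not be a vehicle matched in time. An effect shared by the 3 compounds stays open too. Insig1, a sterol-responsive inhibitor of SREBP processing, was 5.37-fold lower (log2 fold -2.42, interval -2.51 to -2.34), and Hmgcs1, an early enzyme of the mevalonate pathway, was 3.38-fold lower. The growth factor-responsive transcription factors Egr2 and Egr1 were 10.9-fold and 3.44-fold lower. Cyp1a1, the classical AhR target, was 8.66-fold higher (log2 fold 3.11, interval 2.45 to 3.85), from 23.1 to 200.5 normalised reads. In all 68 genes passed the size rule, 19 higher and 49 lower, out of 11262 at a mean level of at least 50. At a mean level of at least 10 the balance turned to 125 higher and 113 lower.

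All 24 measured cholesterol synthesis genes were lower in PNU 12 h than in DMSO 12 h, 12 of them at least 2-fold. Their median log2 fold was -1.04, below each of 10000 random lists matched on level. Besides Insig1 and Hmgcs1, the steroid dehydrogenase gene Hsd17b7 was lower (log2 fold -1.41, interval -1.68 to -1.15). Of 28 immediate early genes 25 were lower and 7 were lower at least 2-fold, with a median of -0.70, again below each random list. Fos had a log2 fold of -1.63 (interval -1.91 to -1.36) and Dusp1, a MAP kinase phosphatase, of -1.54 (-1.65 to -1.44). Cyr61, a matricellular gene that is listed with TGF-beta responses, was 4.30-fold lower, and Edn1, which encodes endothelin-1, 2.91-fold lower. Fgl2 was 3.50-fold lower, from 78.7 to 22.5 normalised reads. The BMP and TGF-beta list had a median of -0.24 with 18 of 22 genes lower, led by Cyr61 and Ctgf (-1.16). The list of feedback genes of ERK signalling had a median of -0.24 with 12 of 18 lower, among them Spry2 (-0.98) and Dusp5 (-0.96). The calcium and cAMP response list had a median of -0.27, with 13 of 18 lower, among them Pde4b (-0.90) and Nr4a1 (-0.74).

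On the other side, 5 of the 7 measured AhR and xenobiotic genes were higher in PNU 12 h, 3 of them at least 2-fold, with a median of 0.88 above each of the random lists. Cyp1b1 was 2.19-fold higher (log2 fold 1.13, interval 1.05 to 1.21), Nqo1, a quinone reductase, 2.03-fold higher, and Aldh3a1 had a log2 fold of 0.88. Slc14a1, a urea transporter, was 2.65-fold higher, Bdkrb1, a bradykinin receptor, 2.51-fold, the matrix metalloproteinase Mmp10 2.24-fold and the small GTPase Rab25 2.04-fold. Ribosomal protein genes were slightly higher, with 41 of 45 above 0 and a median of 0.15, as were nuclear genes of oxidative phosphorylation, with 36 of 44 above 0 and a median of 0.12. Both medians lay above each of the random lists. Such ranks were common: of 33 lists, 5 lay below and 4 above the rank limits given for the simulation. In PNU 30 min against DMSO 12 h, with 6 genes past the size rule, 6 of 33 lay below and 5 above. The fewest were in nicotine 12 h against 1 h, with 1 below and 1 above of 34. Random lists were matched on level only, so a rank, here and below, says little by itself about a small median. Ribosomal protein genes have many near-identical copies in the genome, so their values are uncertain. The NF-kB and inflammation list had a median of 0.16, above 9990 of the random lists, although its members with the largest differences, Nfkbiz (-1.12) and Cxcl1, were each at least 2-fold lower. Of 13438 genes in the authors' deposited table, 0 had an adjusted p-value under 0.05 and 101 an unadjusted p-value under 0.05.

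Nicotine, an agonist of many nicotinic receptors, was the positive control of receptor activation. Nicotine 12 h against DMSO 12 h gave 51 genes past the size rule, 13 higher and 38 lower. Insig1 was 7.57-fold lower (log2 fold -2.92, interval -3.02 to -2.82) and Hmgcs1 3.66-fold lower. Egr2 was 4.87-fold, Cyr61 4.51-fold, Egr1 3.81-fold, Fos 3.18-fold and Dusp1 3.05-fold lower. The ciliary dynein gene Dnai2 was 3.33-fold and the phosphodiesterase gene Pde10a 3.21-fold lower, both at under 150 normalised reads in DMSO 12 h. Cyp1a1 was 9.31-fold higher (log2 fold 3.22, interval 2.56 to 3.96), Slc14a1 3.60-fold, Cyp1b1 2.94-fold and Nqo1 2.03-fold higher. The glutamate transporter gene Slc17a6 (2.36-fold), the serpin Serpinb2 (2.26-fold), Perp (2.14-fold), the chemokine Ccl7 (2.10-fold), the NADPH oxidase Nox1 (2.06-fold) and the alcohol dehydrogenase Adh7 (just past 2-fold) were also higher. All 24 cholesterol synthesis genes were lower, 14 at least 2-fold, with a median of -1.14. Of 28 immediate early genes 27 were lower, 11 at least 2-fold, with a median of -0.85, and all 7 AhR genes were higher, with a median of 0.89. Each of these 3 medians lay outside all 10000 random lists.

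Smaller list differences in nicotine 12 h against DMSO 12 h included the G2/M genes, 32 of 43 higher with a median of 0.12 (Anln 0.52, Mki67 0.30). Genes encoded by the mitochondrial genome had a median of 0.13, with 12 of 13 higher. For the G2/M and the mitochondrial list, nicotine 12 h was the highest of all libraries against the median library (0.14 and 0.17). Its share of mitochondrial reads was also the highest, at 3.58%. The ER stress list had a median of -0.12 (20 of 31 lower, Atf3 -1.40, Chac1 -0.67), and the hypoxia and glycolysis list a median of -0.11 (25 of 31 lower). The circadian list had a median of -0.24 (13 of 17 lower), and Bhlhe40 (-1.18) led both of those lists. The glucocorticoid list also had a median of -0.24, led by Dusp1, which is an immediate early gene too. The ERK feedback list had a median of -0.18 and the NF-kB list a median of 0.17. For this pair the authors' deposited table held 0 genes at an adjusted p-value under 0.05 and 78 at an unadjusted one under 0.05.

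MLA 12 h against DMSO 12 h, the negative control, gave 44 genes past the size rule, 10 higher and 34 lower. The leading genes were again Insig1 (7.59-fold lower; log2 fold -2.92, interval -3.02 to -2.83), Hmgcs1 (4.00-fold) and the sterol oxidase Msmo1 (3.18-fold). Egr2 was 4.42-fold, Cyr61 4.19-fold, Egr1 3.11-fold, Dusp1 2.96-fold and Edn1 2.86-fold lower. Gramd2 was 2.79-fold lower, from 76.2 to 27.3 normalised reads. Cyp1a1 was 8.79-fold higher (log2 fold 3.14, interval 2.48 to 3.87), the hydroxycarboxylic acid receptor Hcar2 3.14-fold, Slc14a1 2.98-fold, Cyp1b1 2.71-fold, Bdkrb1 2.35-fold, the cohesin gene Rec8 2.24-fold and Wnt10a 2.22-fold higher. All 24 cholesterol synthesis genes were lower, 13 at least 2-fold, with a median of -1.16. Of 28 immediate early genes 25 were lower, 7 at least 2-fold, with a median of -0.66, and all 7 AhR genes were higher, with a median of 0.90. The balance of directions turned with the rule, to 143 higher and 116 lower at 1.5-fold and to 139 and 84 at a mean level of at least 10.

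In the same comparison the NF-kB list was higher, with 18 of 24 genes above 0 and a median of 0.26 (Birc3 0.97, Ccl7 0.93). The list of mesenchymal and matrix genes had 25 of 33 above 0 and a median of 0.18 (Tnc 0.57, Fn1 0.46), and the Notch list 12 of 14 above 0 and a median of 0.29 (Notch1 0.53, but Hes1 -0.66). The ER stress list had a median of -0.11 with 24 of 31 lower (Atf3 -1.20), and the glucocorticoid list a median of -0.20. Ribosomal protein genes (40 of 45 lower, median -0.09) and nuclear oxidative phosphorylation genes (42 of 44 lower, median -0.09) lay on the opposite side of 0 from PNU 12 h. Adjusted p-values in the authors' deposited table were under 0.05 for 0 genes, and unadjusted ones for 94.

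These 3 comparisons use the same DMSO library. Of 11187 genes measured in all, 25 were lower and 5 were higher at least 2-fold in PNU 12 h, nicotine 12 h and MLA 12 h alike. The 25 lower genes included Egr2, Insig1, Cyr61, Egr1, Hmgcs1, Fos, Dusp1, Edn1, Hsd17b7, Msmo1, Cyp51, Scd2, Fdft1, Fdps, Idi1, Lss, Fads1, Sqle, Ctgf and Zfp36. The 5 higher genes were Cyp1a1, Slc14a1, Bdkrb1, Cyp1b1 and Hcar2. Independent lists of these lengths would share 0.000399 lower and 2.73e-05 higher genes, and simulated unchanged libraries set against 1 shared control shared a mean of 0.07 genes. PNU 12 h and nicotine 12 h shared 26 lower and 6 higher genes (0.144 and 0.0306 for independent lists, 0.14 in total in the simulation), and PNU 12 h and MLA 12 h shared 28 and 5 (0.127 and 0.0170, and 0.13). Across genes, which are not independent replicates, the log2 folds of PNU and MLA correlated with r = 0.57, against 0.53 in the simulation, with a covariance of 0.0317 against 0.0179, a difference of 0.0138. For PNU and nicotine r was 0.35 against 0.52, with a covariance of 0.0211 against 0.0179, a difference of 0.00319. The single DMSO library could not be split, so the overlap holds whatever is particular to it. With PNU 30 min in place of DMSO 12 h as the reference, an alternative chosen after seeing the data, 15 of the 30 shared genes passed the size rule in PNU 12 h, 20 in nicotine 12 h and 17 in MLA 12 h.

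**Figure D2:**
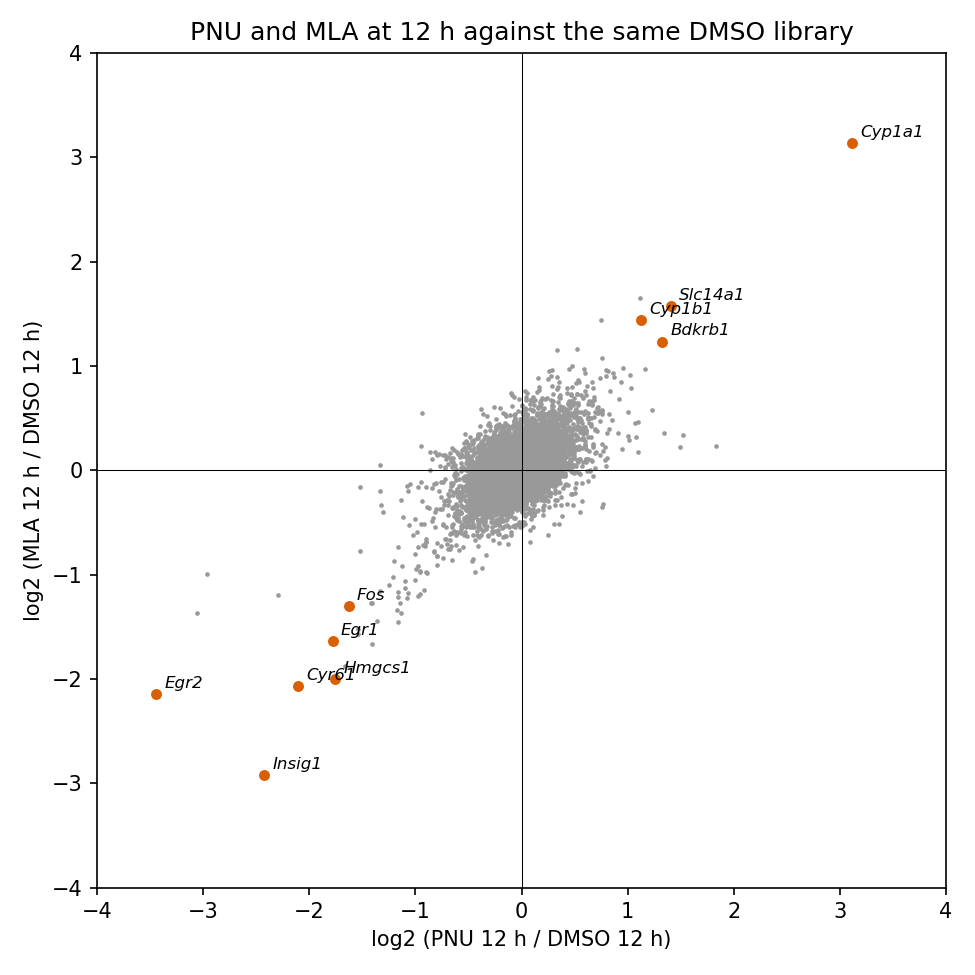
Log2 fold of each gene in PNU 12 h (horizontal) and MLA 12 h (vertical) over the same DMSO 12 h library, for genes at a mean level of at least 50 normalised reads (grey points; orange points are the genes named in the plot). Cyp1a1 lay at 3.11 and 3.14, and Insig1 at -2.42 and -2.92.

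The PNU time course asked how the profile differed from 30 min to 12 h of the agonist. AhR targets were higher at later times and cholesterol synthesis genes lower, while Egr1 was lowest at 1 h. The series holds no vehicle library at 30 min to 8 h, so time in culture and PNU cannot be told apart here. Cyp1a1 stood at 28.3 normalised reads at 30 min, 83.4 at 1 h, 289 at 3 h and 188 at both 8 h and 12 h, against 21.5 in DMSO 12 h. Cyp1b1 stood at 2659, 3522, 9018, 5567 and 4289 in the same order. Insig1 stood at 4755, 4334, 3324, 716 and 1156, and Hmgcs1 at 8607, 8150, 5119, 2171 and 2973. Egr1 stood at 2945, 665, 2332, 1434 and 1596, against 5448 in DMSO 12 h. Bdkrb1 stood at 27.3 at 30 min and was highest at 3 h, at 95.1, and the adaptor gene Dok3 went from 33.6 at 30 min to 109 at 3 h. In MLA, the negative control, Insig1 was also lower at 12 h (811) than at 1 h (3144), while Cyp1a1 stood at 273 at 1 h and 189 at 12 h. In nicotine Insig1 was low at both times (782 and 816).

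Of 11188 genes, 197 had a range of at least 2-fold over the 5 PNU libraries. Of these 71 were highest at 8 h, in the shallowest library, 48 at 3 h, 34 at 30 min, 23 at 1 h and 21 at 12 h. Without PNU 3 h, an alternative chosen after seeing the data, there were 103 such genes.

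**Figure D3:**
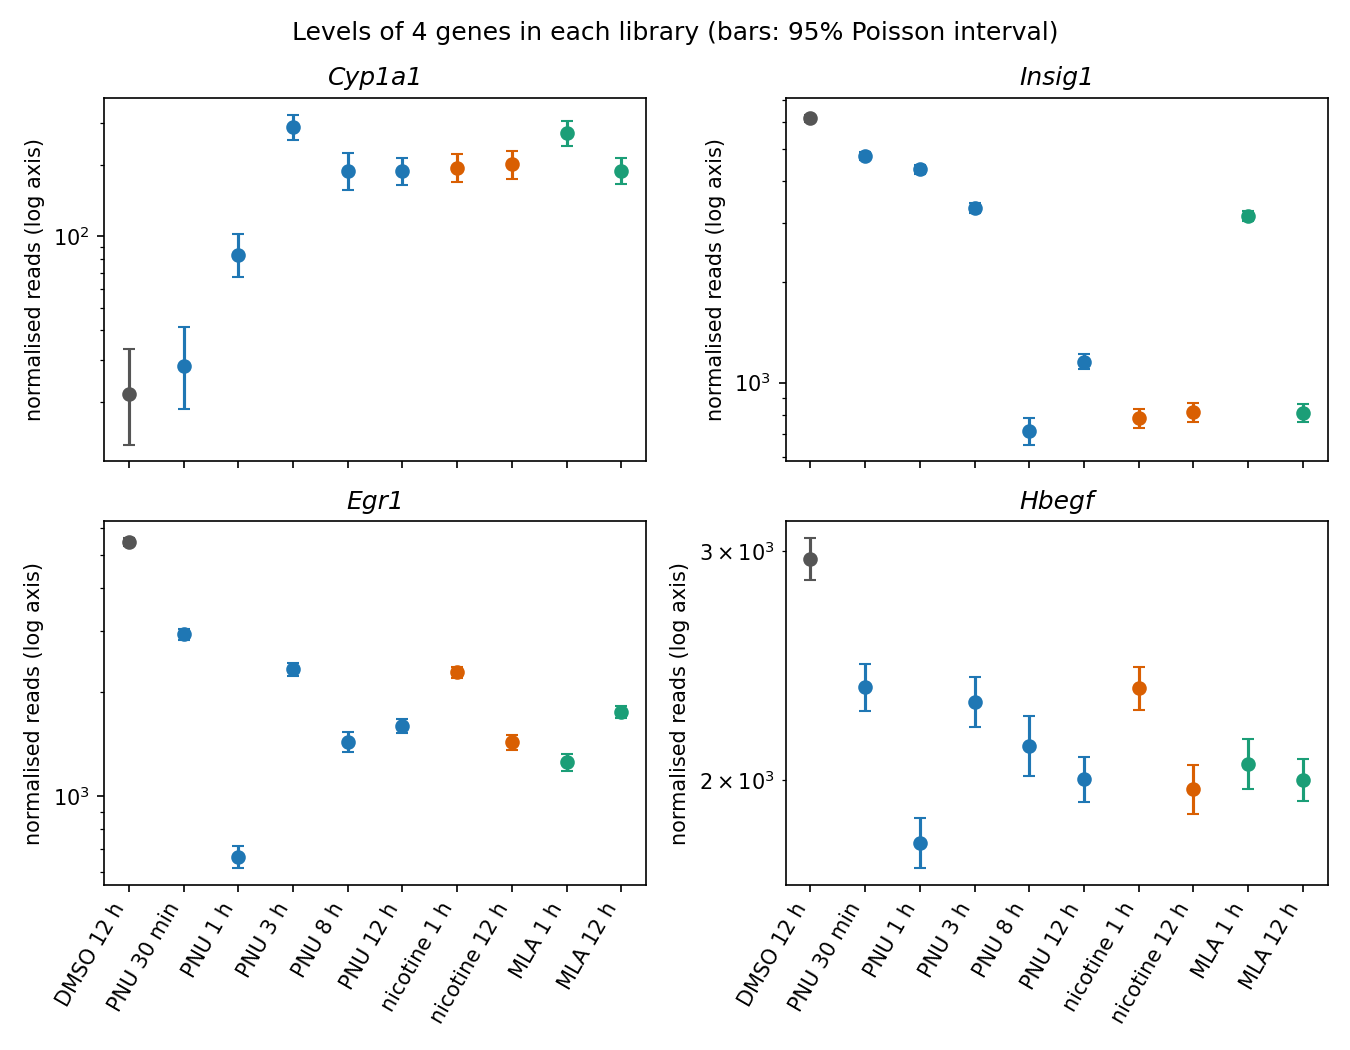
Normalised reads (log axis) of Cyp1a1, Insig1, Egr1 and Hbegf in each of the 10 libraries (horizontal axis; grey DMSO, blue PNU, orange nicotine, green MLA), with 95% Poisson intervals of the counts as bars. Cyp1a1 was lowest in DMSO 12 h (21.5) and PNU 30 min (28.3), and Insig1 was highest in the same 2 libraries (6156 and 4755).

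Set against DMSO 12 h, at times that do not match except for 12 h, the PNU libraries gave 6 genes at 30 min (0 higher, 6 lower), 28 at 1 h (2 and 26), 49 at 3 h (30 and 19) and 51 at 8 h (21 and 30). At 30 min Egr2 was 2.05-fold lower, and the median of the immediate early list was -0.35, with 26 of 28 lower. At 1 h Egr1 was 8.22-fold lower (log2 fold -3.04, interval -3.15 to -2.93), Egr2 6.32-fold, Fos 3.77-fold, the chemokine Cxcl1 2.93-fold, the NF-kB regulator Nfkbiz 2.72-fold and the phosphatase Dusp6 2.70-fold lower. The NF-kB list as a whole had 14 of 22 genes above 0 and a median of 0.09, above 9953 of the random lists, while its mean was -0.17. Cyp1a1 was 3.86-fold higher. The cholesterol list had a median of -0.14 at 30 min, -0.15 at 1 h, -0.41 at 3 h and -1.15 at 8 h. The AhR list had medians of 0.31, 0.56, 0.83 and 0.65 in the same order.

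At 3 h Cyp1a1 was 13.4-fold and Cyp1b1 4.63-fold higher than in DMSO 12 h, followed by Bdkrb1 (3.53-fold), Trim72 (2.98-fold), the adhesion molecule L1cam (2.75-fold), Rec8 (log2 fold 1.42), Slc14a1 (1.41), Atoh8 (1.36) and the Notch ligand Dll3 (1.35). Egr2 (5.25-fold), the arrestin family gene Arrdc3 (2.79-fold), the phosphodiesterase Pde4b (2.79-fold) and Ppm1k (2.79-fold) were lower. G2/M genes were lower at 3 h, with 34 of 43 below 0 and a median of -0.18 (Hmmr -0.53, Mad2l1 -0.49). Set against the median library, G2/M genes were lowest in nicotine 1 h (-0.25) and PNU 3 h (-0.20), which stood close to each other, and next lowest in PNU 8 h (-0.07). At 3 h the list of progenitor and reprogramming genes had 11 of 15 above 0 and a median of 0.29, above 9952 of the random lists (Notch1 0.69, Nes 0.49). This list too was most extreme in PNU 3 h and nicotine 1 h among the higher libraries, at 0.30 and 0.13 against the median library. The BMP and TGF-beta list had a median of 0.26 at 3 h (Id2 0.86, but Cyr61 -1.04). At 8 h the largest differences were Insig1 (8.59-fold lower), Egr2 (4.85-fold lower), Hmgcs1 (4.59-fold lower), Cyp1a1 (8.75-fold higher), Cyp1b1 (2.86-fold higher) and Rab25 (2.74-fold higher). At 8 h the mesenchymal and matrix list had a median of 0.22 (Snai1 0.87, Tnc 0.67) and the Notch list of 0.33 (Notch1 0.63, Hes1 -0.72). Ribosomal protein (median -0.19) and oxidative phosphorylation genes (-0.18) were lower at 8 h, where at 12 h they were higher. At 1.5-fold the balance at 8 h turned to 235 higher and 138 lower, and at a mean level of at least 10 to 125 and 114. Across these 4 comparisons the authors' deposited tables held 0 genes at an adjusted p-value under 0.05, and in order of time 17, 4, 99 and 74 at an unadjusted one under 0.05.

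**Figure D4:**
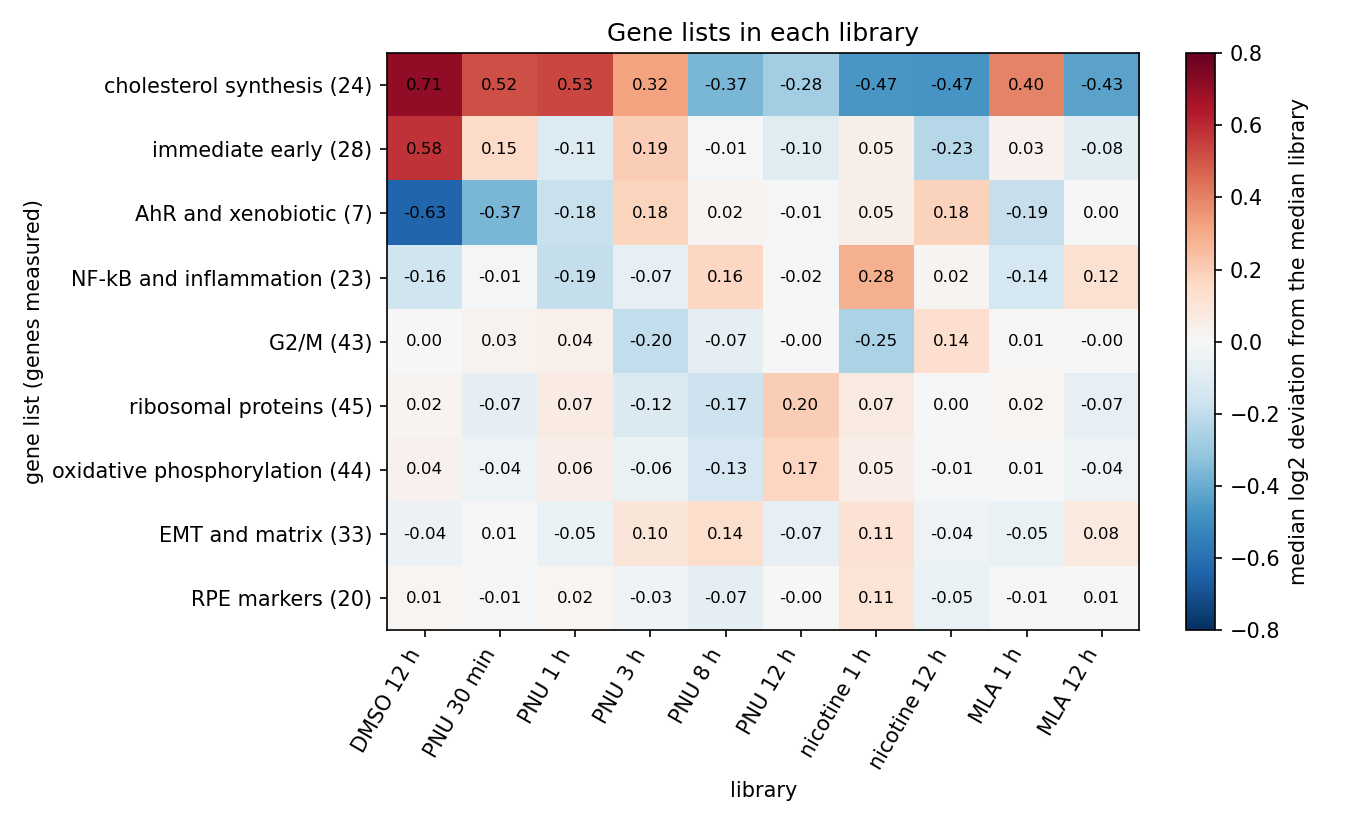
Median log2 deviation of 9 gene lists (rows, with the number of genes measured) from the median library in each of the 10 libraries (columns; red higher, blue lower). Cholesterol synthesis genes stood at 0.71 in DMSO 12 h and at -0.28 to -0.47 in PNU 8 h, PNU 12 h, nicotine 1 h, nicotine 12 h and MLA 12 h.

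PNU and MLA were compared at the same dose and time. At 1 h they differed in 11 genes, 3 higher and 8 lower in PNU. The AhR targets Cyp1a1 (3.26-fold; log2 fold -1.71, interval -2.07 to -1.35), Cyp1b1 (2.31-fold) and Tiparp (2.16-fold) were lower in PNU 1 h than in MLA 1 h. Ccno, Spry4, Bsn and Cxcl1 were between 2.01-fold and 2.07-fold lower, and Ggn (2.10-fold), the retinaldehyde reductase Dhrs3 (2.03-fold) and Cyp4f17 (2.03-fold) were higher. Cholesterol synthesis genes were slightly higher in PNU 1 h (23 of 24, median 0.21), as were interferon-responsive genes (30 of 39, median 0.18; Gbp2 0.40). Immediate early genes were lower (18 of 28, median -0.16; Egr1 -0.91). The fibroblast list had a median of 0.24 over 5 genes, led by Col3a1 (0.50). Ribosomal protein and oxidative phosphorylation genes had medians of 0.04 and 0.07.

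At 12 h PNU and MLA differed in 18 genes, 6 higher and 12 lower in PNU. Itgb8, an integrin that activates latent TGF-beta, was 2.60-fold lower (log2 fold -1.38, interval -1.98 to -0.80), the matrix gene Fras1 2.35-fold, the kinase Nrk 2.25-fold, Gfod1 2.09-fold, Lrrc58 2.05-fold and Vwa5a 2.05-fold lower. Ribosomal protein genes were higher in PNU 12 h (43 of 45, median 0.27), as were nuclear oxidative phosphorylation genes (42 of 44, median 0.22) and ER stress genes (30 of 32, median 0.18; Ddit3 0.71, Trib3 0.61). The NF-kB list (22 of 23 lower, median -0.20), the BMP and TGF-beta list (22 of 23 lower, median -0.17), the Notch list (13 of 14 lower, median -0.22) and the mesenchymal and matrix list (22 of 33 lower, median -0.15; Col3a1 -0.59) lay on the other side. Cholesterol genes were slightly higher in PNU 12 h (median 0.16; Insig1 0.51, interval 0.39 to 0.62). At 1 h and 12 h alike the authors' deposited tables held 0 genes at an adjusted p-value under 0.05, with 48 and 103 at an unadjusted one under 0.05.

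PNU and nicotine were compared at the same times but at different doses, 100 nM and 1 µM. At 1 h they differed in 148 genes, 107 higher and 41 lower in PNU, the largest of the 4 comparisons between compounds. Insig1 was 5.52-fold higher in PNU 1 h than in nicotine 1 h (log2 fold 2.47, interval 2.36 to 2.57), Hmgcs1 4.40-fold and Msmo1 2.92-fold higher. All 24 cholesterol synthesis genes were higher, 13 at least 2-fold, with a median of 1.04. The p53 target Tp53inp1 (3.32-fold), Dhrs3 (3.20-fold), Vps13a (3.12-fold), Avl9 (2.94-fold), Klhl24 (2.92-fold) and Crebrf (2.89-fold) were also higher in PNU 1 h. The histone gene Hist1h1b (3.68-fold), Egr1 (3.44-fold), Rab25 (2.85-fold), Kif26b (2.59-fold), Zbtb20 (2.57-fold), Cpne5 (2.56-fold), Phlda1 (2.54-fold), Hcar2 (2.52-fold) and Spry4 (2.49-fold) were lower. The NF-kB list (21 of 23 lower, median -0.57; Cxcl2 -1.20, Ccl2 -0.97), the AhR list (4 of 7 lower, median -0.61; Cyp1a1 -1.23), the immediate early list (median -0.29) and the ERK feedback list (median -0.23) were lower in PNU 1 h. G2/M genes (36 of 43 higher, median 0.25) and circadian genes (13 of 17 higher, median 0.31) were higher. Nicotine 1 h stood apart from the other libraries, as given above.

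At 12 h PNU and nicotine differed in 52 genes, 7 higher and 45 lower in PNU. Itgb8 was 3.33-fold lower in PNU 12 h (log2 fold -1.73, interval -2.34 to -1.16), the kinase Wnk3 3.02-fold, Vwa5a 2.44-fold, the junction protein Cxadr 2.40-fold, the Hippo pathway gene Mob1b 2.30-fold, Agps 2.26-fold, the chloride channel Clcn5 2.24-fold, Trove2 2.21-fold, Ptbp3 2.21-fold and Sema3d 2.21-fold lower. Hoxb8 was 2.06-fold higher, as was Rplp2 (2.11-fold), a ribosomal protein gene. Ribosomal protein (42 of 45 higher, median 0.18), oxidative phosphorylation (39 of 44, median 0.16), ER stress (26 of 32, median 0.20; Ddit3 0.62) and immediate early genes (23 of 28, median 0.16) were higher in PNU 12 h. G2/M genes were lower (31 of 43, median -0.15; Anln -0.57). Wnk3, Cxadr, Mob1b, Agps, Trove2 and Ptbp3 were also among the genes with the largest loadings on the first component of all libraries, given below. On it nicotine 12 h lay at -0.38 and PNU 12 h at 0.19. Between PNU and nicotine the authors' deposited tables held 0 genes at an adjusted p-value under 0.05, with 171 at 1 h and 126 at 12 h at an unadjusted one under 0.05.

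Each compound was also compared between 12 h and 1 h, without use of the DMSO library. PNU gave 30 genes, 9 higher and 21 lower at 12 h. Insig1 (3.77-fold lower), Fgl2 (3.63-fold), Hmgcs1 (2.76-fold), the phosphatidate phosphatase Lpin1 (2.70-fold), Itgb8 (2.54-fold) and Gas1 (2.44-fold) were lower at 12 h. Egr1 (2.39-fold), Cyp1a1 (2.24-fold), Rab25 (2.13-fold) and the chemokine Cxcl2 (2.01-fold) were higher. MLA gave 17 genes, 4 higher and 13 lower, with Insig1 (3.87-fold), Tiparp (2.56-fold), Hmgcs1 (log2 fold -1.32), Ccno (2.44-fold), Msmo1 (2.32-fold), the fructose transporter Slc2a5 (2.23-fold) and Cyp51 (2.23-fold) lower and Wnt10a (2.71-fold), Apom (2.11-fold) and Tldc1 (2.08-fold) higher. All 24 cholesterol synthesis genes were lower at 12 h in both compounds, with medians of -0.83 in PNU and -0.75 in MLA. The NF-kB list was higher at 12 h in both, with medians of 0.25 and 0.37, and the BMP and TGF-beta list lower, with medians of -0.32 and -0.18 (Id2 -0.93 and -0.84). At a mean level of at least 10 the balance of directions turned to 106 higher and 76 lower in PNU and to 66 and 58 in MLA. For PNU the authors' deposited table held 0 genes at an adjusted p-value under 0.05 and 80 at an unadjusted one under 0.05, while the nicotine and MLA values come from levels scaled over all libraries, since no table used here pairs their 1 h and 12 h libraries.

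Nicotine 12 h against nicotine 1 h gave 294 genes, 246 higher and 48 lower. Mob1b (3.78-fold), Trove2 (3.64-fold), Ptbp3 (3.63-fold), Avl9 (3.63-fold), Vps13a (3.56-fold), Rictor (3.55-fold), an mTOR complex subunit, and Xiap (3.51-fold), a caspase inhibitor, were higher at 12 h. Zbtb20 (2.60-fold), Hist1h1b (2.52-fold), Fjx1 (2.49-fold), Rec8 (2.42-fold) and the Wnt target Axin2 (2.24-fold) were lower. G2/M genes were higher at 12 h (33 of 43, median 0.41; Anln 1.04) and immediate early genes lower (25 of 27, median -0.35). These 2 libraries lay at opposite ends of the first component of all libraries (0.66 for nicotine 1 h and -0.38 for nicotine 12 h), with PNU 3 h at 0.45. Mob1b, Trove2, Ptbp3, Avl9, Vps13a, Rictor, Xiap, Zbtb20 and Rec8 were among the genes with its largest loadings. The share of mitochondrial reads was 3.03% in nicotine 1 h and 3.58% in nicotine 12 h. No gene passed the size rule in the same direction between 12 h and 1 h in all 3 compounds (0 of 11067). Independent lists would share 6.83e-05 lower and 6.40e-05 higher genes. PNU and MLA, which share no library here, had 7 lower genes in common against 0.0183 for independent lists, among them Insig1, Hmgcs1, Ac1576, Fdft1, Cyp51 and Msmo1. The log2 folds of these 6 in nicotine lay between -0.11 (Cyp51) and 0.57 (Hmgcs1). Insig1 was low in nicotine 1 h already, at 782 normalised reads, against 4334 in PNU 1 h and 3144 in MLA 1 h.

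For completeness, nicotine 1 h and MLA 1 h were set against DMSO 12 h, at times that do not match. Nicotine 1 h gave 153 genes, 36 higher and 117 lower. Insig1 was 7.87-fold, Hmgcs1 5.40-fold and Msmo1 3.73-fold lower, and Cyp1a1 9.06-fold, Bdkrb1 3.88-fold, Hcar2 3.64-fold and Slc14a1 3.17-fold higher. The cholesterol list had a median of -1.23, the AhR list of 1.06 and the NF-kB list of 0.39 (Traf1 1.22, Relb 1.21). MLA 1 h gave 27 genes, 10 higher and 17 lower, with Cyp1a1 (12.6-fold), Cyp1b1 (4.19-fold) and Tiparp (3.31-fold) higher and Egr2 (4.78-fold), Egr1 (4.35-fold) and Cyr61 (2.90-fold) lower. The cholesterol list had a median of -0.31 in MLA 1 h, and the balance of directions there turned to 126 higher and 85 lower at 1.5-fold and to 94 and 84 at a mean level of at least 10. For these 2 pairs the authors' deposited tables held 0 genes at an adjusted p-value under 0.05, with 164 and 73 at an unadjusted one under 0.05.

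RPE markers had medians of -0.08 in PNU 12 h, -0.10 in nicotine 12 h and -0.01 in MLA 12 h against DMSO 12 h. Only 20 of the 34 RPE markers were measured over all libraries, so these values do not describe the rest of the list. Best1, a chloride channel gene of the pigment epithelium, lay between 4756 and 7060 normalised reads, Krt8 between 3557 and 4215, Pmel between 479 and 574 and Mitf between 131 and 180. The photoreceptor gene Sag was low, at 15.2 to 39.8 normalised reads. Of the leukocyte markers Cd14 lay between 552 and 714, Cd68 between 82.9 and 162 and Ptprc between 70.8 and 124, and of the endothelial markers Flt1 lay between 95.9 and 181 and Cdh5 between 7.37 and 24.3. Vim and Col1a1, listed as glial and fibroblast markers, were abundant in each library, at 42078 to 63596 and 21518 to 48344, and these genes are also expressed by cultured epithelial cells. Col1a1 was highest in PNU 3 h (48344) and nicotine 1 h (45305) and lowest in nicotine 12 h (21518). The endothelial list had a median of 0.92 in PNU 8 h against DMSO 12 h, over 5 genes and above 9983 of the random lists, with Flt1 at 0.92. The glial list had a median of -0.19 in PNU 1 h against DMSO 12 h, over 9 genes and below 9961 of the random lists.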

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

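The tests of the late culture state, of both label swaps, of depth and of a shared direction were chosen only after the result was seen; the test of a few genes taking most of the reads was set before. The 7 entries below moved in opposite directions between 12 h and 1 h in 2 compounds, each past the size rule, with 1 library per condition, and the difference was not tested. Itgb8 had a log2 fold (12 h over 1 h) of -1.34 in PNU and 1.59 in nicotine. Nrk had -1.01 in PNU and 1.11 in nicotine. LOC100911204 had -1.15 in PNU and 2.88 in nicotine. AABR07000398.1 had 1.16 in PNU and -2.12 in nicotine. AABR07063425.1 had 1.73 in PNU and -1.60 in nicotine. Apom had -1.12 in nicotine and 1.08 in MLA. AABR07015081.2 had -1.69 in nicotine and 1.05 in MLA. Nicotine was on 1 side of each of these pairs. Over all genes its 12 h over 1 h folds also ran against those of PNU (r = -0.51, 31.7% with the same sign) and MLA (r = -0.40, 33.2%). Genes of independent sign would give 50%, but genes are not independent replicates, and each fold is of 1 pair of libraries. Nicotine 1 h (0.66) and nicotine 12 h (-0.38) lay at opposite ends of the first component, so these values may restate the place of those 2 libraries.

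The nicotine 1 h library stood apart from the other 1 h libraries. On 17 genes chosen from PNU 30 min, 8 h and 12 h alone, with PNU 30 min set at 0 and PNU 12 h at 1, it lay at 1.18, against 0.123 for PNU 1 h and 0.377 for MLA 1 h; without the cholesterol list (9 genes) these were 1.10, 0.131 and 0.550, so the early position of MLA 1 h rests on cholesterol genes. Nicotine 12 h lay at 0.970 (0.697 without the cholesterol list), so a swap of the nicotine labels would still leave a 1 h library at a late position. Such a swap alone therefore does not account for the pattern. It cannot be excluded, since nicotine itself may give a late position at 1 h, in which case both nicotine libraries lie late with or without a swap. A swap with DMSO 12 h stays open, since on 13 of the 17 genes DMSO 12 h lay under 0.5 and nicotine 1 h over 0.5. A late culture state, from a wrong label or later collection, may also account for the position of 1.18, and so may nicotine itself, which these libraries cannot separate from it.

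Nicotine 1 h and PNU 3 h shared a deviation, and had the 2 largest values on the first component of all libraries (48.8% of the variance), 0.66 and 0.45. Depth and a few genes taking most of the reads are argued against, since the reads of PNU 3 h in listed genes (20740579, or 20.7 M) and the share of the 10 most abundant genes in nicotine 1 h (4.93%) lay within the range of the other libraries, as did the same measures of the other library of the 2. The share of mitochondrial reads was lowest in these 2 libraries (2.98% in PNU 3 h and 3.03% in nicotine 1 h, against 3.12% to 3.58% in the others) and highest in nicotine 12 h; what this share reflects was not tested. The differences nicotine 1 h minus MLA 1 h and PNU 3 h minus PNU 30 min, which share no library, correlated across genes with r = 0.648. Each sets a library high on the component against a low one (MLA 1 h -0.30, PNU 30 min -0.20), so this value largely restates the component. Nicotine 1 h and PNU 3 h may share a direction of variation of unknown origin. It is not confined to them, since nicotine 12 h (-0.38) and MLA 1 h (-0.30) lay at the other end of the component and nicotine 12 h minus MLA 12 h gave r = -0.524, and time is not set aside, since 1 of the differences is between times; the labels give no batch, and no biological explanation was tested.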

How the results depend on the processing

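The alternatives without single libraries, with PNU and MLA only, with PNU 30 min in place of DMSO 12 h, and all those for the PNU time course were chosen only after the result was seen. Recentring on the median gene and folds taken through another library left each of the 16 comparison counts within 1.5 times its value. Both shift all genes of a comparison by the same small amount, since the tables hold the same reads. They could hardly change the counts, so this says little about how firm the counts are. Lists outside the random ranks in PNU 12 h against DMSO 12 h numbered 9, 9 and 10 under 3 alternatives, against 9. The 423 other values recomputed, of lists and of the genes at the top of each ranking, kept their direction. Most of them were recomputed with a pseudocount or with the small shifts above. These can hardly reverse a fold past 2-fold, so the count says little about how firm the directions are. Named genes further down the rankings were not recomputed, so those of low level may also fall below 2-fold. With a pseudocount of 10, which shrinks folds of low genes, 16 of the 138 named folds recomputed fell below 2-fold. These were Mmp10 in PNU 12 h, Bdkrb1 in MLA 12 h and Egr2 in PNU 30 min (against DMSO 12 h), Ggn, Dhrs3, Cyp4f17, Ccno and Spry4 (PNU and MLA at 1 h), Fras1 and Gfod1 (PNU and MLA at 12 h), Hoxb8 and Rplp2 (PNU and nicotine at 12 h), and Rab25 and Cxcl2 in PNU and Apom and Tldc1 in MLA (12 h against 1 h). The counts depended on the fold and level required; looser rules pass more genes by construction. At 1.5-fold the counts against DMSO 12 h were 327 (PNU 12 h), 269 (nicotine 12 h), 259 (MLA 12 h), 85 (PNU 30 min), 140 (PNU 1 h), 554 (PNU 3 h), 373 (PNU 8 h), 963 (nicotine 1 h) and 211 (MLA 1 h). Against PNU they were 1000 (nicotine 1 h), 138 (MLA 1 h), 532 (nicotine 12 h) and 262 (MLA 12 h), and between 12 h and 1 h 234 (PNU), 1646 (nicotine) and 151 (MLA), with 1 gene in all 3 compounds, a median of 277 over pairs of libraries and 1656 in the time course. At a mean level of at least 10, where counting error is larger, the counts against DMSO 12 h were 238, 222, 223, 134, 152, 263, 239, 411 and 178 in the same order. Against PNU they were 416, 150, 250 and 177, between 12 h and 1 h 182, 558 and 124, and in the time course 1037. The larger direction turned from lower to higher under both rules in MLA 12 h, PNU 8 h and MLA 1 h against DMSO 12 h, and at a mean level of at least 10 in PNU 12 h (125 higher, 113 lower) and between 12 h and 1 h in PNU (106 and 76) and MLA (66 and 58). At a mean level of at least 200 there were 37 genes in PNU 12 h and 27 in MLA 12 h. With PNU 30 min as reference there were 26 in nicotine 12 h, 24 in MLA 12 h and 48 in PNU 12 h; the cause was not tested. Without PNU 3 h the time course gave 103 genes, without nicotine 1 h and PNU 3 h the median over pairs was 24.5, and PNU and MLA alone shared 7 genes between 12 h and 1 h, where fewer libraries take part. Leaving out a replicate was not run, with 1 library per condition. Depth limits genes near a mean level of 10, where the intervals are wide.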

Other observations

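The tests on the position of DMSO 12 h and on scaling were chosen only after the result was seen. The lists not given in the report had these medians in PNU 12 h against DMSO 12 h. EGF family genes had a median of -0.19 (9 of 13 lower), glucocorticoid genes of -0.18 (9 of 11), FGF genes of -0.17 (5 of 8), circadian genes of -0.14 (14 of 17) and JAK-STAT genes of -0.06 (14 of 20). Medians were 0.09 for Wnt targets, 0.08 for progenitor genes, 0.06 for ER stress genes, and 0.05 for Notch and heat shock genes. They were -0.06 for p53 targets, -0.03 for hypoxia and glycolysis, and -0.02 for NRF2 and for mesenchymal and matrix genes. Medians lay between -0.01 and 0.02 for interferon, S phase, G2/M, mitochondrially encoded, glial, neuron and nicotinic and muscarinic receptor genes, and stood at 0.08 for photoreceptor and 0.05 for immune markers. With 4 members measured in each, metallothionein genes had a median of 0.12, fibroblast markers of -0.11 and endothelial markers of 0.61.

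DMSO 12 h lay apart from the treated 12 h libraries on the genes of the PNU time axis, and less clearly over all genes. It differed from them in 41 (MLA), 51 (nicotine) and 62 (PNU) genes at 2-fold, against 0 (MLA and nicotine), 13 (MLA and PNU) and 48 (nicotine and PNU) among the treated libraries. At 1.5-fold these were 241, 270 and 310, against 59, 222 and 470. The authors' scaling is argued against, since a scaling factor shifts all genes alike and the median of the cholesterol list minus that of the AhR list was -1.91 in PNU 12 h against DMSO 12 h. On the 17 genes of the PNU time axis DMSO 12 h lay at -0.046, against 0.921 for MLA 12 h and 0.970 for nicotine 12 h (0.152, 0.877 and 0.697 without the cholesterol list). A culture state near the start of a treatment, from a wrong label, early collection or no change of medium, may account for this. An effect shared by the 3 compounds, agonists and negative control alike, stays open and untested, since there is 1 vehicle library.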
